A study of Mus musculus with 2 samples.

How the data were processed

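Trimethylation of lysine 9 on histone H3 (H3K9me3), a mark of silent chromatin, was mapped by chromatin immunoprecipitation and sequencing in mouse lung at embryonic day 16.5. Per the labels, lungs of male and female B6NCrl embryos were pooled, the library size range was 300 to 500 bp, and 2 biological replicates of a single group were made. Replicate 1 had 2 technical replicates and replicate 2 had 1, and the label of replicate 2 names 41 pooled embryos. The labels contain no second condition, so no condition was compared.

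The measurements were 4 peak lists on the mm10 assembly, in the narrowPeak format per the file descriptions deposited with the samples. The authors called 1 list on each replicate alone and 1 on both replicates pooled, and deposited a list of replicated peaks that was derived from the other 3 lists. The replicate 1 list was derived from its alignments and 2 further input files, the replicate 2 list from its alignments and 1 further input file, and the pooled list from both alignments and 2 further input files, per the deposited descriptions, which do not say what these inputs are. The peak caller, its version, its threshold, the aligner and the rule for a replicated peak are not given in the sources used here. Each deposited peak carries a display score and a signal value, which is the peak's enrichment as the authors' caller gave it, with no unit stated (treated as a score). The −log10 p and −log10 q of each peak are also the authors' deposited values. Read depth is unknown, so no interval that needs it is given, and signal values were used only to describe, rank or filter peaks within a list.

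Peaks were analysed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. A pair of peaks was counted as shared when they had at least 1 bp in common. Genes, exons and transcription starts were taken from GENCODE mouse release M21 and sequence from the GRCm38 reference, which is the mm10 build. Coordinates are 1-based. Gene comparisons used the 21 assembled chromosomes, and peaks on unlocalized or unplaced scaffolds were left out of them.

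The replicated list was the main list for location and genes. Each observed value was compared with 9999 circular shifts, in which all peaks of a chromosome moved by 1 random offset on the circle from the first to the last base covered by any list. This keeps peak widths, numbers and clustering. The permutation p-values speak of position only, not of the spread among embryos or pools. They were two-sided, with 0.0002 as the smallest possible value, except for the one-sided replicate overlap, with 0.0001. Base composition and the classes of gene that include pseudogenes used 999 shifts, with 0.002 as the smallest value. Adjusted p-values are Benjamini-Hochberg values within a family. Features were assigned by peak midpoint in the order promoter (1 kb either side of a transcription start), exon, intron and between genes. A gene counted as marked when its body shared at least 1 bp with a peak. Peak position along zinc finger genes was tested by permuting gene labels 100000 times. Peaks within 5 kb were merged into domains, and 999 random placements of single peaks served as their background.

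Gene lists were fixed before the data were examined. They comprised zinc finger genes, vomeronasal and olfactory receptors, clustered protocadherins, imprinted genes, germline genes, X-linked germline families and tandem gene families (together and as 11 single families). They also comprised markers of lung epithelium, lung mesenchyme, endothelium and blood, genes of nerve, liver and muscle or heart, pluripotency genes, Hox genes, ribosomal protein genes, housekeeping genes and genes of the H3K9me3 machinery, which makes 31 lists. Of the 28 listed symbols of the machinery, 27 were found; all symbols of the other lists given by name were found. Lists overlap little: zinc finger and imprinted lists share 2 genes, zinc finger and pluripotency lists 3, germline and imprinted lists 1, germline and ribosomal lists 1, and liver and Serpin lists 1. Genes named below were chosen by a rule fixed at the same time. It took the first 20 protein-coding genes under the replicated peaks with the highest signal that overlapped both replicates, up to 4 members of each list by covered length, genes in the 10 domains with the most covered length, and 12 imprinted genes whatever their values.

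The methods were tested on simulated peaks. In 50 shifted lists without enrichment, each tested with 499 shifts, 27 of 1550 list tests had an unadjusted p below 0.05 (1.74%). These lists and their background were shifts of the same peaks, so a low rate was built in. It checks the calculation only and cannot show that shifts are a fair background for real peaks. No run gave an adjusted call. With 499 shifts, however, the smallest possible p of a lone gene list stays above 0.05 after adjustment over 31 lists. The absence of adjusted calls therefore cannot show how often the adjusted threshold gives false calls. With an extra peak planted in 20% of a list, the zinc finger list (427 genes) was found in 20 of 20 runs, the germline list (50 genes) in 20 and the imprinted list (58 genes) in 17, at unadjusted p. With 10% these counts were 20, 10 and 8. The position test, on 1800 simulated genes, was positive in 3 of 50 runs without a difference and in 50 of 50 with 55% of peaks in the terminal part. The simulated genes had few and independent peaks, unlike overlapping genes in the data, which share many. The rate of false calls with such shared peaks was not measured. The overlap test was positive in 3 of 50 runs without shared positions and in 50 of 50 with 5% of peaks at their real positions. The runs without shared positions likewise compared shifts with shifts of the same peaks. Overlap counts equalled those of bedtools 2.31.1 in 8 of 8 comparisons.

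Alternatives were the list of each replicate alone, the pooled list, a −log10 q of at least 2, the stronger 50% of peaks by signal, the list without its 50 strongest peaks, and other definitions of overlap, promoter, marked gene, domain and background. Added after seeing the data were overlap on assembled chromosomes alone, replicated peaks that overlap a peak of both replicates, and the last exon as the terminal part of a gene.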

Results

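The 2 replicates of embryonic day 16.5 lung yielded H3K9me3 peak lists of very different length. The list of replicate 1 held 59211 peaks covering 16.7 Mb and that of replicate 2 held 3582 peaks covering 1.08 Mb, a ratio of 16.5 in number. The pooled list held 20257 peaks (6.41 Mb) and the replicated list 13560 peaks (4.87 Mb). Peaks were narrow, with a median width of 229 bp in replicate 1, 233 bp in replicate 2 and 284 bp in the replicated list, of which 348 peaks (2.57%) exceeded 1 kb. A −log10 q of at least 2 was reached by 19569 peaks of replicate 1, 476 of replicate 2 (13.3%) and 4277 of the replicated list (31.5%). Signal is the authors' peak value and was used only within a list. The lists give no read depth, and with 1 list per replicate no SD between replicates is given.

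The strongest sites were shared by both lung pools. The peak with the highest signal in the replicated list that overlapped both replicates covered most of Klf14 (chromosome 6, 30956473 to 30958843), an imprinted intronless gene for a Krüppel-like transcription factor, with a signal of 19.6 and a −log10 q of 65.4. Of the 100 strongest peaks of replicate 1, 90 were found in replicate 2, and of the 100 strongest of replicate 2, 99 were found in replicate 1. Over the whole lists, 2984 of 3582 replicate 2 peaks (83.3%) lay in the replicate 1 list, whereas 2698 of 59211 replicate 1 peaks (4.56%) lay in the replicate 2 list. On the assembled chromosomes the share of replicate 2 peaks found was 82.6%, against a mean of 1.39% in shifted lists (SD 0.253, highest 4.36%), 59.6 times as many (one-sided permutation p = 0.0001, the smallest possible). With replicate 1 reduced to as many top peaks as replicate 2 has, the share was 35.0%, against a shifted mean of 0.126%. The strongest of 10 equal signal classes of replicate 1 was overlapped at 21.2%, the next at 7.23% and the other 8 at 0.760% to 3.60%.

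**Figure D1:**
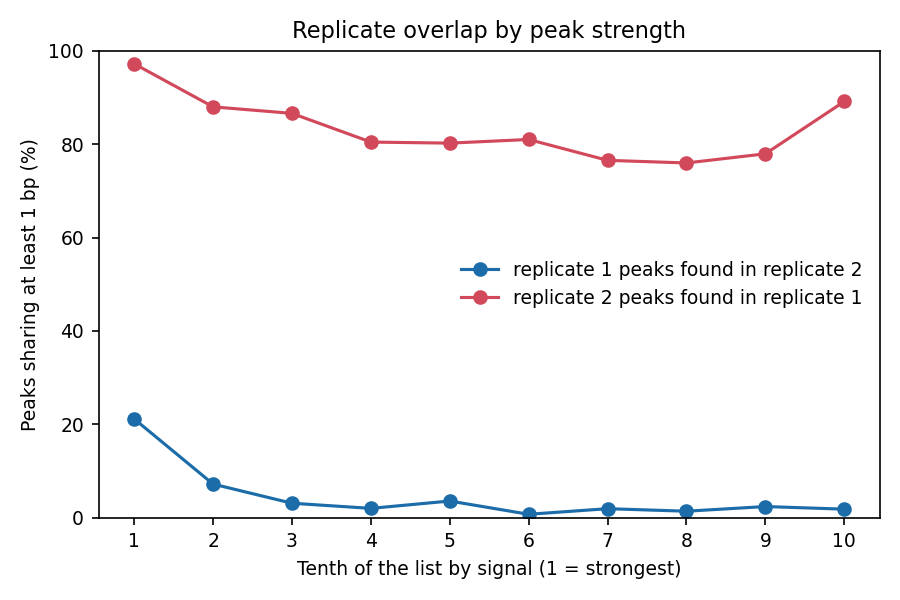
Share of peaks (%) that share at least 1 bp with a peak of the other replicate, by signal class within each list, from the strongest (1) to the weakest (10). The replicate 1 line lies at 21.2% in class 1 and at 1.86% in class 10, and the replicate 2 line lies between 76.0% and 97.2%.

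Most replicated peaks overlapped a peak of replicate 1 alone. The 13560 peaks all had the name and position of a pooled peak and made up 66.9% of the pooled list. A peak of replicate 1 was overlapped by 93.0% of them and a peak of replicate 2 by 21.4%. Both replicates supported 2633 peaks (19.4%, 95% Wilson interval 18.8 to 20.1, counting error only), replicate 1 alone 9972 (73.5%), replicate 2 alone 263 (1.94%) and neither 692 (5.10%). Among the 4277 replicated peaks with a −log10 q of at least 2, both replicates supported 46.4%. Of the pooled peaks left out of the list, 13 of 6697 overlapped both replicates.

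After Klf14, the strongest shared peak in a gene lay in Mid1 on the X chromosome (169988480 to 169989576, exonic, signal 11.8), which encodes a ubiquitin ligase. It was followed by peaks at Tcfl5 (chromosome 2, 180642600 to 180643948, signal 11.3), Gm44973 (chromosome 7, 5028871 to 5032474, 10.8) and Asmt, which encodes the last enzyme of melatonin synthesis (chromosome X, 170674236 to 170675347, intronic, 10.2). Zfp68 (signal 9.88), Zfp873 (9.40), Zfp777 (8.62), Zfp930 (8.62), Zfp810 (8.54) and Zfp37 (8.15) were the zinc finger genes among the 20. Mest, a paternally expressed imprinted gene, had a signal of 8.46. Peaks inside other genes included those in Shroom3, which encodes an actin regulator of cell shape (signal 9.56), Spred2, an inhibitor of Ras signalling (9.22), Arl5a (9.09), Habp4 (8.93), Nphp4, a ciliary gene (8.48), and Col13a1, a transmembrane collagen (8.31). The peaks at Tcfl5 and Gm21887 (signal 8.52) had their midpoints outside the gene. At Gm21887 the −log10 q was 75.5, the highest of the list, against 16.2 at Zfp777 and 18.4 at Zfp810 with like signal. At Mid1 the −log10 q was 61.4, against 30.4 at Tcfl5. The remaining gene was Gm42416 (8.68), whose annotated body spans the protocadherin clusters on chromosome 18.

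Imprinted genes carried the mark more often than chance. Of 58 listed genes, 39 (67.2%) overlapped a replicated peak, against a mean of 10.4 in shifted lists, 3.74 times as many (adjusted permutation p = 0.00207). Some listed genes overlap one another, as Airn does Igf2r, so 1 peak can mark several and the 39 need not be separate sites. The shifts keep such overlaps. Gnas, which encodes the alpha subunit of the stimulatory G protein, had 7 peaks covering 10.3 kb (5 in both replicates). Airn, the non-coding RNA antisense to Igf2r, had 8 peaks covering 6.35 kb (1 in both). Grb10, a growth factor receptor adaptor, had 5 peaks (4.76 kb, 3 in both) and Mest 5 (4.47 kb, 3 in both). The annotated start of Peg3 lay inside a peak found in both replicates (chromosome 7, 6729847 to 6730569), as did those of Nnat (chromosome 2, 157558483 to 157560649) and Peg10 (chromosome 6, 4746481 to 4748964). The start of Meg3 lay inside a peak (chromosome 12, 109540570 to 109541563) that did not overlap both replicates. A peak in both replicates lay 0.014 kb from the start of Airn and 0.236 kb from that of Kcnq1ot1, the non-coding RNA of the Kcnq1 cluster. Starts were the outermost annotated ones, and other promoters of these genes were not considered. The start of Gnas lay 0.01 kb from a peak, that of Grb10 9.998 kb, that of Mest 11.9 kb, that of Plagl1 28.95 kb and that of Snrpn 79.4 kb. Of these peaks, only the one nearest the start of Grb10 overlapped both replicates. H19 had no peak in its body, and the nearest to its start, 1.89 kb away, was in both replicates. With promoters alone, 19 of 58 were marked, 24.8 times the shifted mean, and with peaks in both replicates 28 of 58, 10.2 times (adjusted permutation p = 0.0031 and 0.00207). The ratio was 1.85 with the replicate 1 list and 8.01 with the replicate 2 list.

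**Figure D2:**
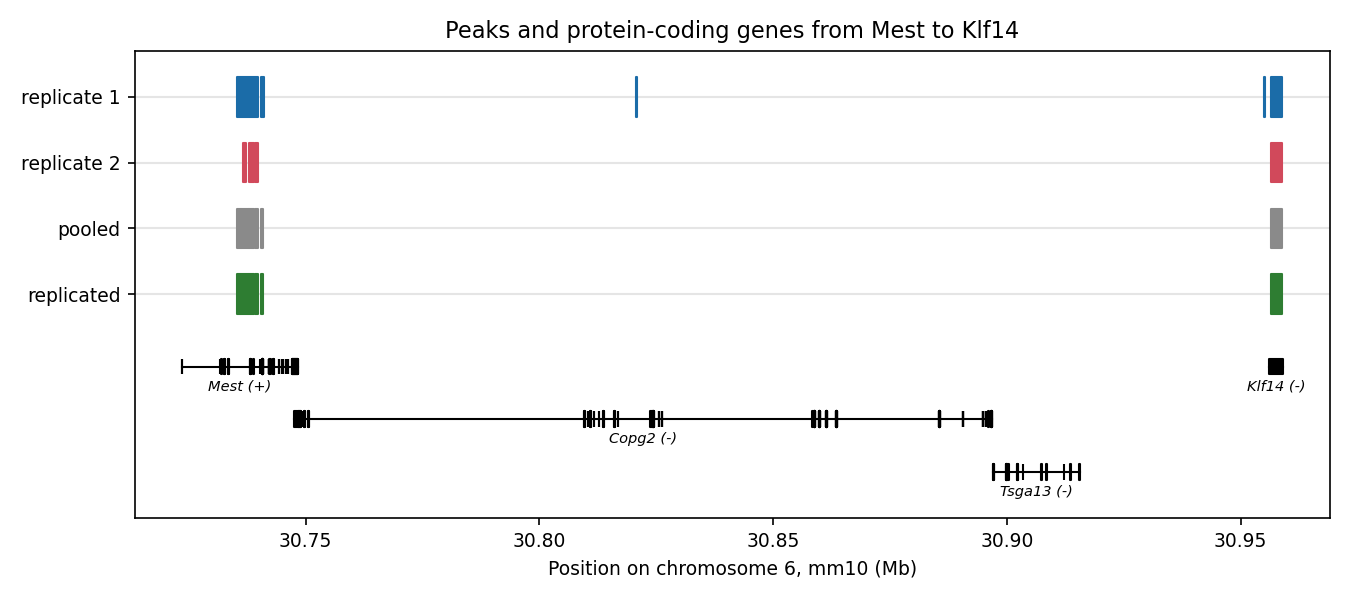
Map of chromosome 6 (mm10, position in Mb) from Mest to Klf14, with the peaks of the 4 lists as coloured boxes and protein-coding genes in black (boxes are exons, the sign is the strand). The replicated list has 6 peaks here, inside Mest and Klf14, and none inside Copg2 or Tsga13.

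Zinc finger genes were marked widely and towards their ends. Of 427 genes, 147 (34.4%) overlapped a replicated peak against a shifted mean of 47.5, 3.10 times as many (adjusted permutation p = 0.00207). Zfp873 on chromosome 10 had 17 peaks covering 11.2 kb, Zfp110 14 peaks (10.8 kb), Zfp68 16 (9.32 kb) and Zfp606 16 (9.08 kb). In peaks found in both replicates, 98 genes were marked, 8.84 times the shifted mean, and the ratio was 1.56 with the replicate 1 list and 7.20 with the replicate 2 list. Promoters were not marked above chance, with 6 of 427 genes and a ratio of 1.03 (adjusted permutation p = 1). Of 491 peak midpoints in 145 zinc finger genes, 55.8% lay in the last of 3 equal parts of the gene. Of 6160 in other protein-coding genes 30.6% did, a difference of 25.2 percentage points (two-sided permutation p = 1e-05, the smallest possible). A midpoint inside several overlapping genes was counted once for each, so these are not numbers of separate peaks. The permutation of gene labels took such repeats, as in the clustered protocadherins, as separate. The difference was 19.8 points with the replicate 1 list and 38.9 points with the replicate 2 list. The last exon held 35.4% of the midpoints in zinc finger genes and 4.74% in other genes, a comparison chosen after seeing the data.

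**Figure D3:**
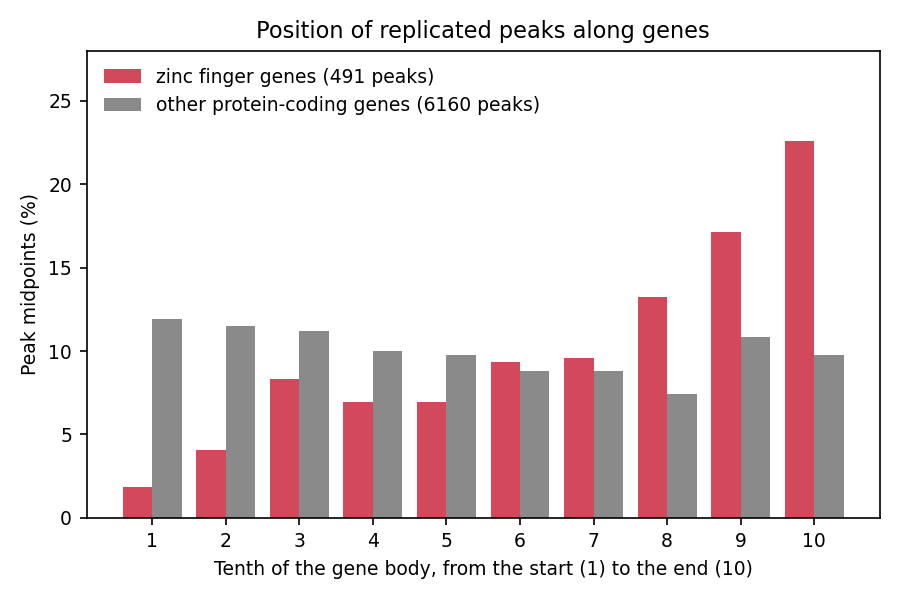
Share of replicated peak midpoints (%) in 10 equal parts of the gene body, from the start to the end. Shown are 491 midpoints in zinc finger genes and 6160 in other protein-coding genes, with a midpoint in several genes counted once for each. The last part holds 22.6% of the zinc finger midpoints and 9.76% of the others, and the first part 1.83% and 11.9%.

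The clustered protocadherins, cell adhesion genes of neurons, were marked as a block. Of 57 genes, 43 (75.4%) overlapped a replicated peak against a shifted mean of 14.3, 3.01 times as many (adjusted permutation p = 0.00775). The annotated bodies of these genes share their ends, so 1 peak marks several. Pcdhga1 had 85 peaks covering 67.2 kb, of which 47 were in both replicates, Pcdhga2 82 (65.5 kb), Pcdhga3 76 (62.0 kb) and Pcdhgb1 72 (58.9 kb). Promoters of 28 of the 57 genes were marked, 38.1 times the shifted mean (adjusted permutation p = 0.0062). The ratio was 1.76 with the replicate 1 list. The call was lost with the replicate 2 list (adjusted permutation p = 0.187, ratio 5.70), with peaks in both replicates (0.192, ratio 7.11), with a −log10 q of at least 2 (0.130, ratio 5.39) and with at least 500 bp covered (0.107, ratio 6.16).

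Germline genes were marked at a higher rate than chance, both over gene bodies and at promoters. Of 50 genes, 17 (34.0%) overlapped a replicated peak against a shifted mean of 6.45, 2.64 times as many (adjusted permutation p = 0.00207). D1Pas1, a testis helicase gene without introns, had 4 peaks covering 1.98 kb. Nlrp5, an oocyte gene, had 6 (1.51 kb, none in both replicates), Taf7l 1 (1.48 kb) and Ddx4, a germ cell helicase gene, 1 (0.893 kb). Promoters of 12 genes were marked, 21.5 times the shifted mean (adjusted permutation p = 0.0031). In peaks found in both replicates 9 genes were marked, 6.31 times the shifted mean, and with the replicate 2 list 10, 5.65 times. The call was lost with the replicate 1 list (ratio 1.29, adjusted permutation p = 0.271) and with a −log10 q of at least 2 (ratio 3.08, 0.093).

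Genes of the lung itself were not marked beyond chance. Among epithelial markers 3 of 32 overlapped a peak (Grhl2, Pdpn and Napsa, shifted mean 3.13), among mesenchymal markers 1 of 24 (Fbln5, 3.46), among endothelial markers 3 of 15 (Pecam1, Flt1 and Tek, 2.98) and among blood genes 0 of 16 (1.46). Among genes of other tissues the counts were 3 of 20 neural genes (Slc17a7, Syt1 and Rbfox3, shifted mean 2.92), 0 of 14 liver genes (0.944) and 3 of 16 muscle and heart genes (1.84). The last included Ttn, the gene of the sarcomere protein titin, with 19 peaks covering 9.02 kb, and Ryr1 and Ckm with 1 each. The ratio of the muscle and heart list was 1.63, with 0.615 in the replicate 1 list and 5.64 in the replicate 2 list. Counts were 1 of 16 for pluripotency genes (Zfp42, shifted mean 1.05), 0 of 39 for Hox genes (1.27), 0 of 79 for ribosomal protein genes (1.84), 1 of 20 for housekeeping genes (Tbp, 1.02) and 3 of 27 for the H3K9me3 machinery (Atf7ip, Smchd1 and Pphln1, 4.70). The adjusted permutation p of these 12 lists was 0.681 or above. Planted peaks were not simulated for these lists.

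With the replicated list and circular shifts, receptor and tandem families did not pass the adjusted threshold. Olfactory receptors were marked in 18 of 1093 genes against a shifted mean of 36.0 (ratio 0.501, permutation p = 0.0294, adjusted 0.152). Their ratio was 1.35 with the replicate 1 list and 0.117 with the replicate 2 list. With a −log10 q of at least 2 it was 0.0891, which passed the threshold (adjusted permutation p = 0.0186). Vomeronasal receptors were marked in 42 of 327 genes (26.1, ratio 1.61, adjusted permutation p = 0.171), led by Vmn1r73 with 4 peaks. Their ratio was 0.554 in peaks found in both replicates. Skint genes were marked in 9 of 11 (3.23, adjusted permutation p = 0.093), led by Skint6 with 18 peaks, none in both replicates. The Ugt family, glucuronosyltransferase genes, was marked in 9 of 19 (3.22, ratio 2.79, adjusted permutation p = 0.61), led by Ugt1a7c with 11 peaks, 8 in both replicates. Its ratio was 0.998 with the replicate 1 list and 10.9 with the replicate 2 list. The 9 marked Ugt genes are Ugt1a genes whose annotated bodies share their end, so 1 domain marks them all. X-linked germline families were marked in 3 of 79 genes (1.40), and with promoters alone also in 3, 13.7 times the shifted mean (permutation p = 0.007, adjusted 0.0543). Counts were 3 of 42 for Defb (shifted mean 0.831), 2 of 31 for Cyp2 (3.88) and 1 of 50 for Serpin (3.37). No gene was marked of 10 Speer, 22 Mup, 57 Krtap, 25 Prl, 15 Sprr and 35 Tas2r genes, and the tandem families together had 24 of 317 (17.4). In all, 4 of 31 lists lay above chance and 0 below at the adjusted threshold, and 6 and 1 at the unadjusted one. Against random lists matched on gene length, vomeronasal receptors (ratio 2.04), Skint (3.12) and Ugt genes (2.86) also lay above and olfactory receptors below (0.544). Such random lists do not keep the clustering of a family's genes, which the circular shifts do. Of 21938 protein-coding genes, 2751 (12.5%) overlapped a replicated peak 897 (4.09%) a peak found in both replicates, 6250 (28.5%) a replicate 1 peak and 1034 (4.71%) a replicate 2 peak.

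**Figure D4:**
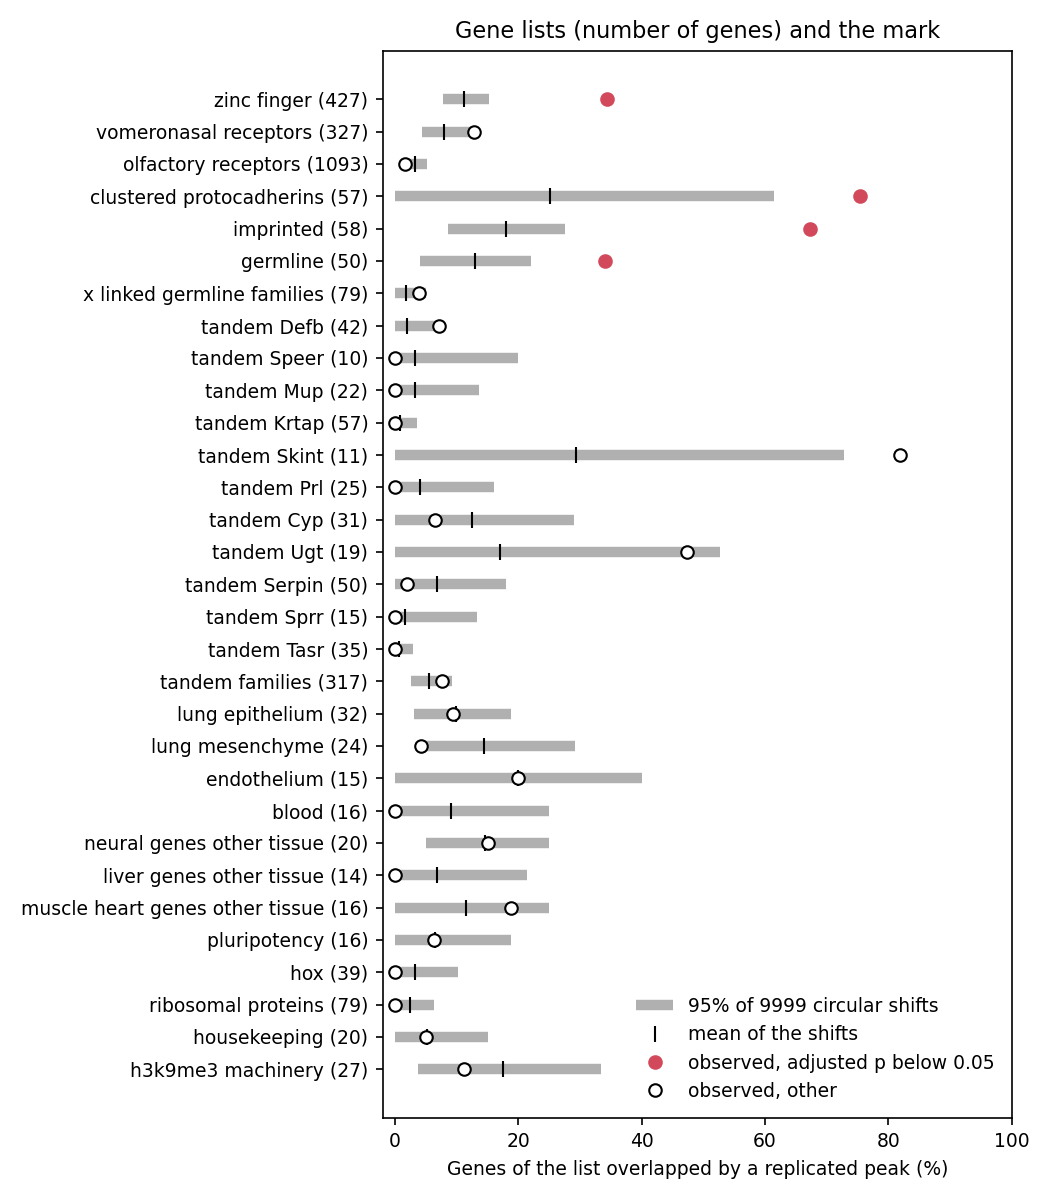
Share of each list's genes (%) overlapped by a replicated peak (points), with the mean (tick) and the central 95% (grey bar) of circular shifts, and the number of genes of the list in brackets. The filled points at 34.4% (zinc finger), 75.4% (clustered protocadherins), 67.2% (imprinted) and 34.0% (germline) have an adjusted p below 0.05.

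Exons held more of the mark than shifted lists, and introns less. Of 13332 replicated peaks on chromosomes, 5.61% had their midpoint in an exon against a shifted mean of 3.22% (SD 0.200, ratio 1.74), and 35.5% in an intron against 40.2% (SD 1.04, ratio 0.882). Both had an adjusted permutation p of 0.0004, from the smallest possible p. The intron call was lost with the replicate 2 list (ratio 0.919, adjusted permutation p = 0.0722), with a −log10 q of at least 2 (0.978, 0.582) and with peaks found in both replicates (0.930, 0.134). Regions between genes held 54.4% against 51.8% (ratio 1.05, adjusted permutation p = 0.0363), and promoters 4.58% against 4.77% (ratio 0.960, adjusted permutation p = 0.512). Directions differed between lists. Promoters held 3.40% of replicate 1 peaks (ratio 0.722) but 7.87% of replicate 2 peaks (ratio 1.66), and regions between genes 61.2% (ratio 1.17) and 44.3% (ratio 0.855), each with an adjusted permutation p of 0.000267. With a −log10 q of at least 2 the ratios were 1.45 for promoters and 0.882 between genes (adjusted permutation p = 0.0004 and 0.000533), and with the pooled list promoters stood at 0.889 (0.0272). Exonic shares were 3.50% in replicate 1 against a shifted mean of 3.18%, and 10.9% in replicate 2 (ratio 3.39).

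The marked sequence was rich in G and C and poor in annotated repeats. GC content of covered bases was 47.2% against a shifted mean of 42.0% (SD 0.208), and the repeat-masked share 26.8% against 33.7% (SD 0.550), each with a two-sided permutation p of 0.002, the smallest possible. GC content was 46.0% in replicate 1 and 48.7% in replicate 2, and the repeat-masked share 28.1% and 23.2%. How the authors treated reads that map to several places is not given in the sources used here, so repeat content is that of called peaks only.

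In the replicated list, chromosomes 7, 17, 5 and 4 had the most called peaks per Mb and the sex chromosomes the fewest. It had 9.02 peaks per Mb on chromosome 7, 1.79 times the mean over chromosomes, 8.51 on chromosome 17 (1.69 times), 7.25 on chromosome 5 (1.44 times) and 6.69 on chromosome 4 (1.33 times). The X chromosome had 1.36 peaks per Mb (0.271 times), with 0.428 times in replicate 1 and 0.324 times in replicate 2, and the Y chromosome had 6 peaks. The order at the top differed between lists. Chromosomes 17 and 18 came first in replicate 2 (1.71 and 1.64 times, with chromosome 7 at 1.55) and among peaks found in both replicates (1.72 and 1.56 times, with chromosome 7 at 1.51). No test was made, since neighbouring peaks are not independent. The dose of the sex chromosomes in pools of male and female embryos and the share of mappable sequence were not accounted for. The mean over chromosomes includes X and Y.

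**Figure D5:**
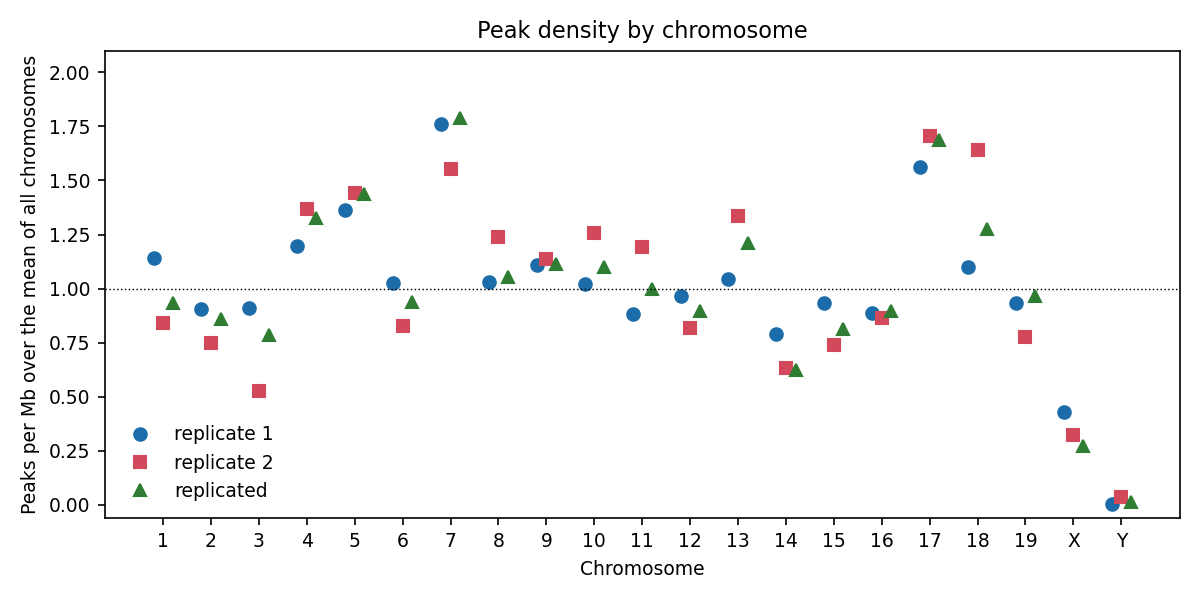
Peaks per Mb of each chromosome divided by the mean over all chromosomes, for replicate 1 (circles), replicate 2 (squares) and the replicated list (triangles), with a dotted line at 1. Chromosome 7 reaches 1.79 in the replicated list, and X lies at 0.428, 0.324 and 0.271.

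The domain with the longest covered length spanned the gamma protocadherin cluster (chromosome 18, 37656713 to 37775587), with 89 peaks covering 68.7 kb, of which 48 were in both replicates. Next came the end of the Ugt1a cluster with Mroh2a (chromosome 1, 88211412 to 88255802, 34 peaks, 34.3 kb, 23 in both), with Trpm8, a cold-sensing ion channel gene, nearby (88282016 to 88310856, 31 peaks, 14.6 kb, 14 in both). Zinc finger genes held the domains at Zfp146 (chromosome 7, 30147496 to 30167794, 15.4 kb), Zfp873 (chromosome 10, 82046684 to 82066466, 13.03 kb) and Zfp110 (chromosome 7, 12836325 to 12853076, 11.5 kb). All 9 peaks of the domain over Sfi1 and Drg1 (chromosome 11, 3184222 to 3200103, 14.1 kb) were in both replicates. Peaks of the domains at Mroh2a, Trpm8 and Drg1 had low signal, with medians of 2.44, 2.37 and 2.70 against 3.43 on chromosomes. Their −log10 q exceeded that of chromosome peaks of like signal in 34 of 34, 30 of 31 and 9 of 9 peaks, and the median −log10 q at Drg1 was 31.4. The domain at AU041133 lay on chromosome 10 (82129186 to 82158754, 10.7 kb). Domains on chromosome 4 (121999387 to 122038509, 11.7 kb) and chromosome 3 (3000108 to 3033126, 10.8 kb) held no protein-coding gene. Merging within 5 kb gave 10247 domains, of which 477 had 3 or more peaks, against a mean of 12.97 (highest 24) in random placements of single peaks. This background moves each peak alone, so narrow peaks split from 1 broad region would also exceed it. The excess does not by itself show clustering of separate sites. The replicate 1 list gave 3380 such domains and the replicate 2 list 150.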

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

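Of the tests in this part, those on shared sites, different sites and input files in the replicates, both on the scaffolds, and the joint one on exons were chosen after the result was seen; the others were set before. The comparisons of genes and chromosomes leave out peaks on unlocalized or unplaced scaffolds, where peaks were called as well: 305 in replicate 1, 164 in replicate 2, 261 in the pooled list and 228 in the replicated list. Per Mb, the replicated list was 8.63 times as dense there as on chromosomes, replicate 1 2.61 times and replicate 2 24.2 times.

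Peaks on scaffolds combined ordinary signal with a −log10 q above that of chromosome peaks (medians of 3.81 and 1.37). Those of the domains at Mroh2a, Trpm8 and Drg1 combined low signal (medians of 2.44, 2.37 and 2.70) with a −log10 q high for that signal. The median −log10 q of these domains was 3.67, 2.52 and 31.4, so in absolute terms it was strong at Drg1 only. At matched signal, the −log10 q of scaffold peaks was higher than that of chromosome peaks by a median of 1.68, and higher in 160 of 228. The median signal of scaffold peaks was 3.48 against 3.43 on chromosomes, inside the 3.23 to 3.60 of random draws of as many chromosome peaks. Both values restate the pattern, so on scaffolds they cannot tell more reads per base in multi-copy sequence from enrichment as strong as elsewhere. Multi-copy sequence stays open for the 3 domains. It also stays open for the peaks at Mid1 and Gm21887, whose −log10 q was high for their signal. The design gives no second group, so no biological explanation was tested.

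Replicate 1 had 16.5 times as many peaks as replicate 2. Pools that carry the mark at different sites are argued against for the strong sites, since 83.3% of replicate 2 peaks and 90 of the 100 strongest replicate 1 peaks lay in the other list; for the weaker peaks of replicate 1 this stays open. For a GC difference between libraries, peaks of replicate 1 that replicate 2 lacks had a lower median GC in each of 5 signal classes. The smallest difference was -1.03 percentage points and the largest -1.39, under the 2 points set in advance. Their single direction leaves a smaller GC difference open, and the GC content of called peaks cannot exclude one without the reads. That replicate 2 recovers only the strong part of one shared set of sites could account for part of the pattern, as its share of replicate 1 peaks fell by 19.3 percentage points from the strongest to the weakest of 10 classes; yet the strongest class was overlapped at only 21.2%, and with replicate 1 reduced to as many top peaks, 35.0% of replicate 2 peaks were found, against 82.6% in the whole list. The lists also differ by 1 further input file and in technical replicates, with 2 for replicate 1 and 1 for replicate 2. Neither difference can be told apart from the replicate, because each list was called with its own libraries and inputs.

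Exons held 1.74 times the shifted share of peaks. Zinc finger and clustered protocadherin genes alone leave a remainder, since without peaks in them the ratio was 1.23 (two-sided permutation p = 0.0014). GC content alone leaves one too, since the exonic share was 1.47 times the mean of draws matched on GC, above the highest draw (5.61% against 4.45%). Both together could account for the excess: without those genes the share was 3.87% against a matched mean of 3.75%, a ratio of 1.03, and the highest matched draw was 4.33%.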

How the results depend on the processing

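The tests on replicated peaks found in both replicates, on assembled chromosomes alone and on the last exon were chosen after seeing the data. Of 477 values under alternatives for 48 results, 371 were counted as kept. With a test, they kept their direction and their side of the threshold, and otherwise they moved little or within their spread. Domain counts of 330 and 583 against 477 were counted as kept. Of the 371, 291 concerned single gene lists and the density of further chromosomes. Many of these lists passed the threshold in neither setting. For the other results, 80 values were kept, 20 moved, 9 reversed, 2 gained a call and 4 lost one. The 371 covered every alternative run for the replicate overlap (35.0% to 94.1%), the exon ratio and the position along zinc finger genes (19.8 to 38.9 percentage points). They also covered every one for the imprinted list (1.85 to 24.8), GC content and repeat content. The lists of the single replicates differ in length, and stricter settings hold fewer peaks; beyond that, the cause was not tested. Read depth is unknown, so what it limits in replicate 2 could not be measured.

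Using the list of 1 replicate alone, support of the replicated list ranged from 21.4% to 93.0%, the density ratio of chromosome 7 from 1.55 to 1.76 and that of X from 0.324 to 0.428, and domains with 3 or more peaks from 150 to 3380. The ratios ranged from 0.722 to 1.66 for promoters, 0.798 to 0.919 for introns and 0.855 to 1.17 between genes. Those of lists ranged from 0.889 to 1.21 for vomeronasal receptors, 0.117 to 1.35 for olfactory receptors, 0.963 to 3.35 for X-linked germline families, 0 to 2.55 for Defb, 0 to 1.30 for Krtap, 0 to 1.03 for Cyp2, 0.998 to 10.9 for Ugt, 0.425 to 1.17 for Serpin, 0 to 3.27 for Tas2r, 0.974 to 2.49 for all tandem families, 0.938 to 1.83 for neural genes, 0.615 to 5.64 for muscle and heart genes and 0 to 1.03 for Hox genes.

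With a −log10 q of at least 2, support by both replicates was 46.4%, the density ratio of chromosome 7 1.45 and of X 0.181, and 138 domains had 3 or more peaks. Ratios were 1.45 for promoters, 0.978 for introns, 0.882 between genes, 0.580 for vomeronasal receptors, 0 for X-linked germline families, 0.837 for endothelium, 2.85 for pluripotency and 1.19 for the machinery, with 2 lists above and 1 (olfactory receptors) below chance. With the stronger 50% by signal, X was at 0.188 and 209 domains were found, with ratios of 1.103 for promoters, 0.989 between genes, 1.06 for lung epithelium, 0.570 for endothelium, 1.69 for pluripotency, 1.80 for housekeeping and 1.11 for the machinery. With the pooled list, 846 domains were found, promoters stood at 0.889 and Tas2r at 3.45.

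With peaks in both replicates, chromosome 7 was at 1.51 and 90 domains were found, with ratios of 1.64 for promoters, 0.930 for introns, 0.854 between genes, 0.554 for vomeronasal receptors, 1.19 for lung epithelium and 0 for X-linked germline families, Defb, Skint and endothelium. With 50% of a peak covered, support by both replicates was 13.5%. A promoter of 2.5 kb gave 1.04 for promoters and 1.05 between genes, the latter no longer past the threshold.

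With promoters alone, ratios were 0.789 for vomeronasal receptors, 3.01 for Cyp2, 1.88 for Serpin, 0.851 for all tandem families, 3.39 for the machinery and 0 for Defb, Skint, endothelium, neural and muscle and heart genes. With 5 kb on either side they were 1.49 for Krtap, 1.19 for lung epithelium, 0.882 for endothelium, 1.12 for housekeeping and 1.29 for the machinery. With at least 500 bp covered they were 0 for X-linked germline families and Defb, 0.888 for endothelium, 3.33 for pluripotency and 1.25 for the machinery. Against random lists matched on gene length, 7 lists lay above and 1 below chance, with ratios of 0.666 for X-linked germline families and 1.00 for pluripotency. The lower share in introns no longer passed the threshold with the replicate 2 list, with a −log10 q of at least 2 or with peaks in both replicates. Promoters and regions between genes passed the threshold in opposite directions in the single replicates, and against the direction of the replicated list with a −log10 q of at least 2 and with peaks in both replicates. No gene list passed the threshold in a setting that turned its direction.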

Other observations

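The genes named in this part were chosen after their values were seen, and the test on processed pseudogenes was set before its value was computed. Outside all fixed lists, peaks found in both replicates also lay in other genes. The zinc finger list went by gene name, so genes outside it can still encode zinc fingers. No shifted mean was computed for single genes, and long genes can hold peaks by chance. Zfhx3 (1019 kb), Sox5 (954 kb) and Cdh4 (457 kb) were the longest of the genes named here. Plec, which encodes the cytoskeletal linker plectin, had 9 peaks covering 7.95 kb (5 in both replicates), and Zfhx3, a homeobox gene, 10 covering 8.75 kb (2 in both). Il3ra, which encodes a cytokine receptor chain, had 8 covering 8.14 kb (5 in both), and Cdh4, a cadherin gene, 14 covering 7.01 kb (7 in both). Polrmt, the gene of the mitochondrial RNA polymerase, had 5 covering 4.69 kb (2 in both), and Sox5, a transcription factor gene, 18 covering 6.43 kb (4 in both).

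Processed pseudogenes, retrocopies of messenger RNAs, overlapped called peaks more often than in shifted lists, which were not matched on GC content. Of 9940 annotated copies, 113 overlapped a replicated peak against a mean of 53.6 in shifted lists, 2.11 times as many (permutation p = 0.002, the smallest possible, adjusted 0.014 over 7 classes of gene). In peaks found in both replicates the count was 28 against 12.6 (ratio 2.22, permutation p = 0.002, the smallest possible, adjusted 0.007). Unprocessed pseudogenes were marked in 63 of 2642 (ratio 1.47, adjusted permutation p = 0.0887) and long intergenic RNAs in 434 of 5854 (ratio 1.11, adjusted permutation p = 0.056). Protein-coding genes as a whole stood at 0.991 times the shifted mean with the replicated list and 1.25 times with peaks in both replicates (adjusted permutation p = 0.007). Whether reads shared between a copy and its parent gene contribute was not tested. Copies in or near zinc finger genes were not left out. The domains at Zfp146, Zfp873 and Drg1 and the one on chromosome 4 without a protein-coding gene each held a processed pseudogene. Whether GC content or such domains account for the excess was not tested either.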
